A study of Mus musculus with 4 samples.

How the data were processed

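RNA from mouse regulatory T (Treg) cells made in culture was measured on 4 single-colour Agilent arrays, 2 from control Junbfl/fl mice and 2 from Junbfl/flCd4-Cre mice, in which Cre recombinase is expressed from the Cd4 promoter in T cells. Groups and array numbers come from the sample titles. Per the labels' protocols, naive CD4 T cells were sorted and kept for 3 days on plate-bound anti-CD3 at 1 μg/ml with anti-CD28 at 0.5 μg/ml, blocking antibodies against IFN-γ and IL-4 at 5 μg/ml each and TGF-β1 at 5 ng/ml. The extraction label names colon as the source of the RNA while the other labels name cultured Treg cells, so markers of colon epithelium and stroma were measured as well. No label says whether the arrays of a genotype came from separate mice or cultures, so the p-values measure the spread between these arrays, which may be technical.

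Per the file headers, each scan was read with Agilent Feature Extraction 11.5.1.1, which gave for each spot a mean pixel intensity, a local background intensity and a processed intensity, background-subtracted and detrended within the array but not scaled between arrays. Spots at or near background carry a small substitute value in place of a subtracted one. The deposited per-spot flags used here were those for a signal well above background, for saturation and for uneven or outlying spots. The series also holds a table deposited by the authors with log2 signals per array, a log2 difference and p-value with Benjamini-Hochberg adjustment for each transcript accession, and the moderated t and log odds scores that limma gives. How the authors made these log2 signals is not given in the sources used here. Their quantiles were nearly the same on the 4 arrays, with a shared maximum of 17.6, and they followed the mean over an accession's probes (Spearman correlation across genes 0.91 to 0.93) more closely than the single probe named beside it (0.84 to 0.87).

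Each array held 62976 spots, of which 59305 were not controls, for 56605 probes. Between 108 and 215 non-control spots per array were flagged as uneven or outlying and left out, and 295 probes without a usable spot on every array were dropped, which left 56310. Spots of a probe were averaged. Gene names were taken from the files and updated through a RefSeq table of assembly GRCm38.p6, used for names only: 32962 probes were named through an accession, 10168 already carried a current symbol, 487 were named through a synonym, and 12693 kept the name in the file. Probe positions are those in the files, on build mm9. The processed signal was put on the log2 scale and the array's 75th percentile over probes was subtracted (processed signals of 151 and 145 on the controls, 119 and 101 on the others). A probe entered if it was well above background on both arrays of at least 1 genotype, and each gene was represented by the probe with the highest mean over the 4 arrays, which gave 22464 names, here called genes.

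The number of arrays limits the precision. Well above background were 60.5% and 59.3% of the non-control spots on controls 1 and 2, and 66.3% and 61.0% on the arrays labelled Junb-deficient 1 and 2. The 75th percentile of the processed signal over all non-control spots was 220 and 207 on the controls and 163 and 138 on the others. No non-control spot was saturated. Repeat spots of a probe had a median SD of 0.036 to 0.039 log2 within an array, against a median SD between arrays of 0.18 in controls and 0.15 in the others.

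The genotypes were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with no covariate, and p-values were adjusted over all genes by the Benjamini-Hochberg method. A gene is called changed at an adjusted p under 0.05. Errors beside log2 differences are standard errors of the fit, with n = 2 arrays per genotype. Groups of 2 are too small for a permutation test to pass 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, for the 26 of 28 lists with at least 3 measured members. Camera at an estimated correlation and fry were alternatives. Camera compares a list with the other genes, while fry tests it against no change, so their calls answer different questions. Where no array of a genotype was well above background for a gene, its signals there were set no lower than the lowest signal well above background on that array, and the difference is given as "at least". Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

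The comparison, the gene lists, the rule for naming genes and most other settings were fixed before the data were examined. The rule names Junb, 18 genes of Treg and helper T cell biology whatever their p, the 12 genes with the largest difference each way among called genes with a plain symbol and no overlap between genotypes, and up to 4 members per list with a p adjusted over the list alone under 0.05, or otherwise up to 2 with the smallest p, given as values. The results of some genes are not reported here. The lists cover AP-1 factors, the Treg signature, the IL-2 receptor, IL-2/STAT5-responsive genes, Th1, Th2, Th17 and Tfh genes, TGF-β signalling, resting T cells, T cell receptor response, inhibitory receptors, homing receptors, apoptosis, cell cycle, glycolysis, cholesterol synthesis, interferon and stress responses, and markers of T cells and of 8 other cell types. The alternatives were other background and scaling methods, the authors' table, other filters and variance models, every probe or the mean of probes, the array number as a block, and each array left out in turn. A floor for dim signals, a filter on repeat and purine-rich probes, quantile normalization with the strictest filter, and the coding-region Junb probe were added after the data were seen.

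The fit was tested on simulated arrays for this comparison with 22464 genes. Of genes changed by 1 on the log2 scale, 0 of 67 were called. Of those changed by 2, 1 of 67 were called, and of those changed by 4, 45 of 66, with 4 false calls. All other genes were unchanged there, so these shares apply where few genes change. With all fitted differences taken as true, noise included, 7276 of 22464 genes were called, 59 of them with the wrong sign. A further simulation shifted the cell cycle list by -1. There camera gave an adjusted p of 1.77e-24 at the preset correlation and 0.18 at the estimated one, which missed the shift. The simulated genes varied independently, so this cannot show how often the preset correlation gives false calls where genes vary together.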

Results

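Gene expression was measured in Treg cells differentiated in culture from naive CD4 T cells of control mice and of mice carrying floxed Junb alleles with Cd4-Cre, 2 arrays each. JunB is a subunit of the AP-1 transcription factor. The series design sets out to describe the Treg cells of the conditional Junb mice, and its title names sensitivity to interleukin-2. Pearson correlations across the 22464 genes were 0.982 between the controls, 0.978 between the arrays labelled Junb-deficient, and 0.933 to 0.955 between genotypes.

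Junb itself was read first, because it checks the labels. The coding-region probe (chromosome 8, 87501881 to 87501940, mm9) had a processed signal of 47.2 and 31.7 on the controls, and of 4.11 and 1.47, not well above background, on the arrays labelled Junb-deficient 1 and 2. It was at least 8.86-fold lower there (adjusted p = 0.0396 when every probe was tested by limma). The brightest Junb probe, at the 3′ end of the transcript (87500843 to 87500902), read 9791 and 9072 on the controls, 1053 on the array labelled Junb-deficient 1 and 10078 on the array labelled Junb-deficient 2. By that probe the log2 difference was -1.10 ± 1.26 (adjusted p = 0.52), and it turned to 0.65 without array 1 and was -2.85 without array 2. The floxed part of the gene is not given in the sources used here, and a probe outside it checks nothing. Because the 3′ probe does not follow the label on 1 array, the genotype is named by its label throughout, and every direction below rests on those labels.

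**Figure D1:**
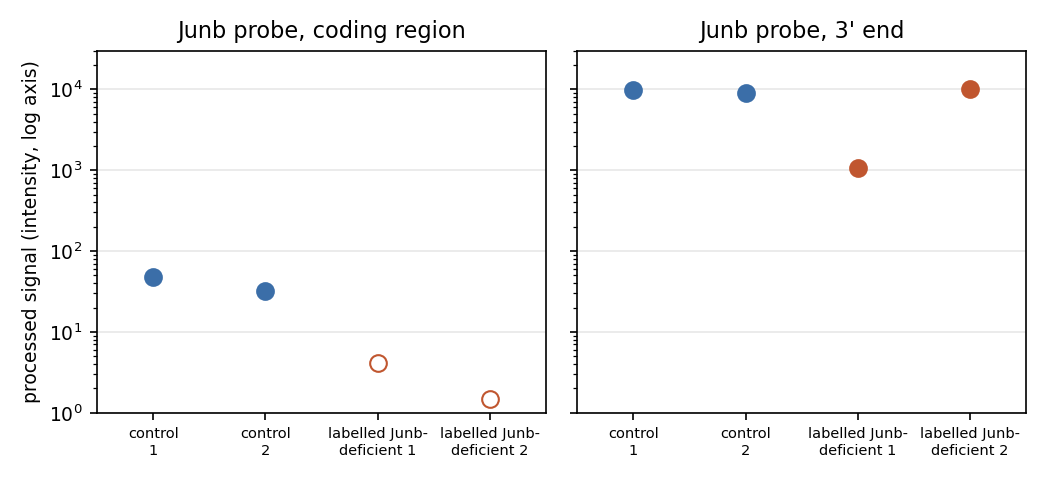
Processed signal (intensity, log axis) of the coding-region and 3′ Junb probes, 1 point per array, open where the signal was not well above background. The coding-region probe read 47.2 and 31.7 on the controls and 4.11 and 1.47 on the arrays labelled Junb-deficient, while the 3′ probe read 10078 on the array labelled Junb-deficient 2, near the controls' 9791 and 9072.

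Il9 and Il17f, cytokine genes of helper T cells, were among the genes that fell most. On the arrays labelled Junb-deficient, Il9 was at least 73.5-fold lower (adjusted p = 0.0289) and Il17a, the main Th17 cytokine, at least 13.7-fold lower (adjusted p = 0.0466). Il17f, its close relative, fell by 6.70 ± 0.40 on the log2 scale, and Ccl20, a ligand of the chemokine receptor Ccr6, fell by 4.92 ± 0.52. Pdpn (podoplanin) was at least 50.4-fold lower, Dsp (desmoplakin) at least 33.1-fold and the noncoding RNA H19 at least 24.7-fold. These bounds hold only for this background treatment and scaling, and the authors' deposited log2 difference for Il9 was smaller, at -3.75. Anxa3, Emp1, Slc4a11, Agap1 and Egln3, an oxygen-sensing prolyl hydroxylase, completed the 12 decreases named by rank, with fitted log2 differences of -5.29, -4.79, -4.64, -4.61 and -4.25. Il17f, Anxa3 and Agap1 were well above background on only 1 of the arrays labelled Junb-deficient, so their exact sizes lean on a reading at background. The calls for Anxa3 and Agap1 rest on their brightest probe, since other probes that were well above background on all 4 arrays gave 0.42 and 0.31.

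Ikzf2, which encodes the Treg transcription factor Helios, rose by 4.56 ± 0.50 on the log2 scale (adjusted p = 0.0324), from processed signals of 69.9 and 26.7 to 801 and 716, the highest fitted difference among called genes with a plain symbol and no overlap between genotypes. Ghrh (4.48), Efna2 (3.88), Arhgap20 (3.71) and Agr3 (3.69) followed among genes seen on a control array, Ghrh on only 1. Sox3, Tmem178, Ly6g6e, Olfr1107, Cap2, Myh7 and Has1 were not well above background on either control, and were at least 10.4, 10.7, 11.8, 15.3, 9.08, 5.60 and 6.22-fold higher. Their processed signals on the arrays labelled Junb-deficient lay between 10.3 and 42.6, against a 75th percentile over probes of 119 and 101. With normexp background, whose offset of 50 compresses dim signals, followed by quantile normalization (the normexp setting below), Sox3, Tmem178, Ly6g6e, Olfr1107, Cap2, Myh7 and Has1 gave 0.47, 0.54, 0.48, 0.67, 0.42, 0.30 and 0.29 and none was called, while Ikzf2 (3.42), Efna2 (2.75), Arhgap20 (1.83) and Agr3 (1.97) still were. Il9 and Il17f remained called at -2.52 and -3.65, and Il17a gave -1.03 and did not (adjusted p = 0.135). Quantile normalization alone left the 7 dim genes between 3.21 (Has1) and 4.03 (Sox3), with Sox3 and Cap2 no longer called. Other probes, taken where the filter differed, gave 0.53 for Myh7, 1.03 for Tmem178 and 2.19 for Ghrh.

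**Figure D2:**
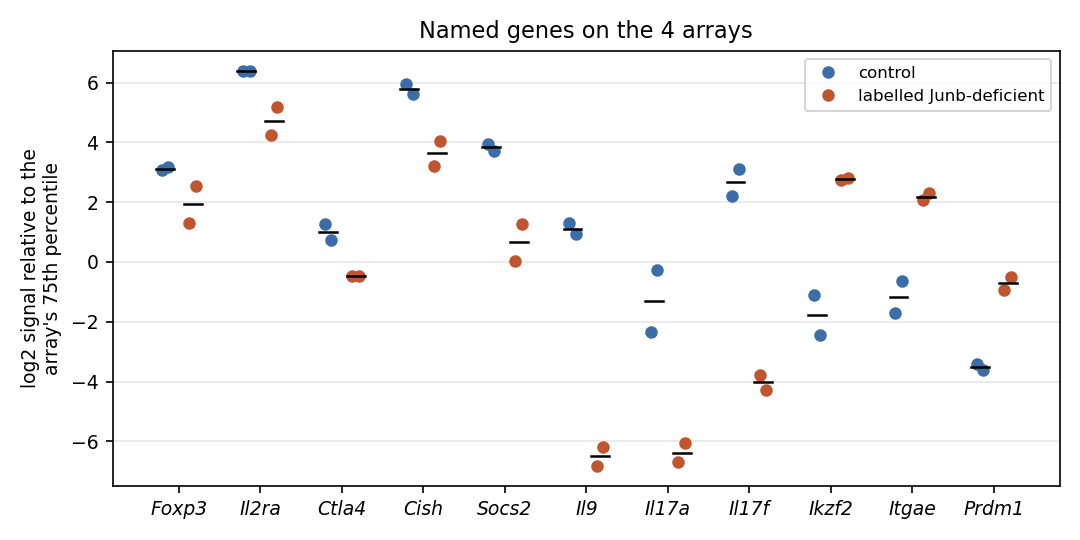
Log2 signal relative to the array's 75th percentile for 11 named genes, 1 point per array with a bar at the mean of each genotype. Il9, Il17a and Il17f lie far lower on the arrays labelled Junb-deficient, Ikzf2, Itgae and Prdm1 lie higher, and for Foxp3 (adjusted p = 0.133) both arrays labelled Junb-deficient lie lower but far apart, at 1.32 and 2.53 against 3.09 and 3.17.

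Of the 22464 genes, 1896 were called, 1576 higher and 320 lower on the arrays labelled Junb-deficient, and with dim signals at their floor 1520 of the higher and 287 of the lower calls differed at least 2-fold. At an unadjusted p under 0.05 there were 9295, of which 5013 were higher and 4282 lower. The genotypes did not overlap in 75.1% of genes. For 1 gene chance gives 33.3%, but differences between whole arrays move many genes together. Setting the 2 shares side by side is therefore no test of genotype. Of the higher calls, 528 were not well above background on either control, and 893 were above it on both. Among the 1172 called genes above background on all 4 arrays, 893 were higher and 279 lower. Without any 1 of the arrays, which leaves 1 genotype with a single array, limma called 0 genes, with 4951 to 8133 at an unadjusted p under 0.05. Of the 58 named genes called, 23 remained called in the same direction with quantile normalization and 20 with normexp background and quantile normalization. The count rests on the scaling, since scaling to the median called 9405 genes of which 21% were higher, against 83.1% here, and quantile normalization called 453 of which 77.7% were higher.

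The Treg signature was not called as a list (28 measured, camera adjusted p = 0.61), and its members went both ways. Its median was -0.53, but -0.16 without control 1, -0.07 with the mean of probes and -0.06 in the authors' table. Over all genes 5 rose and 3 fell, and adjusted over the list alone 7 rose and 6 fell. Ikzf2 rose, as did Itgae (3.36 ± 0.42), the integrin chain CD103, and Prdm1 (2.80 ± 0.22), which encodes Blimp-1, while Socs2, a feedback inhibitor of cytokine signalling, fell by 3.17 ± 0.48. Ctla4, an inhibitory receptor of Treg cells, fell by 1.47 ± 0.23 (adjusted p = 0.0479). Foxp3, the defining transcription factor of Treg cells, gave a log2 difference of -1.20 ± 0.46 that did not pass (adjusted p = 0.133), and was lower in both same-numbered comparisons, by log2 differences of -1.77 and -0.64. Tgfb1 gave -0.47 (adjusted p = 0.132). Il10 was not well above background on both arrays of either genotype and was not tested, nor was Il4.

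Interleukin-2 is named in the series title, and its receptor and targets were measured as separate lists. Of the 12 measured receptor and signalling components none was called, over all genes or over the list alone (camera adjusted p = 0.40). Il2ra, the high-affinity receptor chain CD25, gave -1.67 ± 0.36 (adjusted p = 0.065), Il2 gave -1.69 ± 0.48 (adjusted p = 0.089) and Il2rb, the signalling chain, gave -0.40 (adjusted p = 0.116). The IL-2/STAT5-responsive genes shifted down as a list (median -0.67, camera adjusted p = 0.0078), with 18 of 22 negative (adjusted p = 0.657 with an estimated correlation). Over all genes 4 fell and 2 rose, and adjusted over the list alone 9 fell and 2 rose. Socs2 and Lta (lymphotoxin, -2.75 ± 0.41) fell, and Prdm1 and Il1rl1, the IL-33 receptor (1.87 ± 0.30), went the other way. Cish, another feedback inhibitor, gave -2.15 ± 0.36 (adjusted p = 0.0504 over all genes, 0.0136 over the list alone). Bcl2, a survival factor, gave -1.12 (adjusted p = 0.099).

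Of the helper T cell lists, only Th17 genes were called by camera at the preset correlation. Th17 genes shifted down (median -0.66, mean -1.38, camera adjusted p = 0.0089, adjusted p = 0.657 with an estimated correlation), with 13 of 17 negative, and Il17f, Ccl20 and Il17a were the 3 called over all genes. Maf gave -2.15 (adjusted p = 0.061). Batf and Irf4, AP-1 partners in T cells, gave -0.66 (adjusted p = 0.076) and -1.03 (adjusted p = 0.052). Among 18 Th1 genes (camera adjusted p = 0.235), the receptor chain Il12rb1 fell by 2.79 ± 0.15, Ifng was at least 1.88-fold lower, and Eomes was at least 5.82-fold higher, though in the normexp setting Ifng gave -0.16 and Eomes 0.30, neither called. Nkg7 and Cxcr3 gave 2.28 and -2.24 and passed over the list alone. Tbx21, which encodes T-bet, gave -0.20 (adjusted p = 0.733). Among 13 Th2 genes (camera adjusted p = 0.244), Il9 and the chemokine receptor Ccr4 (-3.42 ± 0.31) fell and Il1rl1 rose, and Gata3 gave 0.83 (adjusted p = 0.068) and Il3 -2.10 (adjusted p = 0.08). No Tfh gene of 12 passed (camera adjusted p = 0.86), with Bcl6 at 1.31 and Cd200 at -1.04.

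The cell cycle list, which also holds the inhibitors Cdkn1a, Cdkn1b and Cdkn2c, gave the smallest camera p-value of the lists at the preset correlation. Fry did not call it (adjusted p = 0.136). All 30 cell cycle genes were measured, 29 were lower, in both same-numbered comparisons, and the list shifted by a median of -1.49 (camera adjusted p = 5.68e-08, adjusted p = 0.657 with an estimated correlation). On the controls the list was higher on number 1 than on number 2 by a median of 0.82 (Cdk1 read 622 and 265), and on the others by 0.10. Over all genes 1 member fell, and adjusted over the list alone 26 fell and 1 rose. Ccna2 and Cdk1, the S and M phase cyclin and kinase, gave -2.11 and -2.05, and Birc5 and Rrm2 each gave -1.86. None of these was called over all genes (limma adjusted p = 0.068, 0.065, 0.0504 and 0.060). The cholesterol synthesis list shifted down with all 20 members negative (median -0.66, camera adjusted p = 3.40e-04, adjusted p = 0.657 with an estimated correlation) and no member called. Sc5d and Srebf2 gave -0.97 and -0.67, and all 20 were higher on number 1 than on number 2 in both genotypes. Glycolysis genes shifted down (median -0.44, camera adjusted p = 0.0078, adjusted p = 0.657 with an estimated correlation), with 5 lower over all genes and 7 lower and 1 higher over the list alone. Tpi1 (-1.50), Eno1 (-1.43) and the glucose transporter Slc2a1 (-1.34) fell, and Hk2 gave -1.38 (adjusted p = 0.053).

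**Figure D3:**
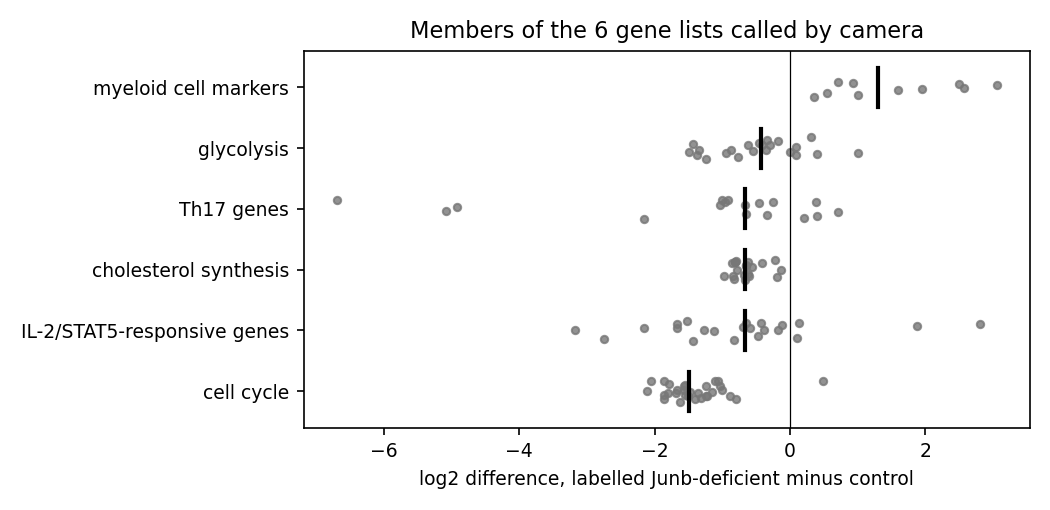
Log2 difference between the arrays labelled Junb-deficient and control for each measured member of the 6 lists called by camera, 1 point per gene with a bar at the list's median. The cell cycle list has a median of -1.49 and the myeloid marker list 1.30.

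These list calls were made at the preset correlation of 0.01. With an estimated correlation limma's camera called 0 of 26 lists, also at an unadjusted p under 0.05. Fry, which tests a list against no change, called 4. These were glycolysis (adjusted p = 0.015) and, outside these 6, Th1 genes (0.042, down), Th2 genes (0.023, down) and colon epithelium markers (0.015, up). In the simulation the estimated correlation also missed a list shifted by design, but the simulated genes varied independently. It therefore cannot show whether the preset correlation gives false calls on these arrays. The estimated correlations were 0.69 for cell cycle, 0.95 for cholesterol synthesis and 0.31 for IL-2/STAT5-responsive genes. For the Th17, glycolysis and myeloid lists they were -0.03, -0.04 and -0.10, below the preset 0.01. A larger correlation therefore does not account for the loss of these calls at the estimated setting. That loss cannot show that they depend on correlation between genes. With quantile normalization the cell cycle and cholesterol calls held, while the IL-2/STAT5-responsive, Th17, glycolysis and myeloid lists gave adjusted p-values of 0.071, 0.053, 0.071 and 0.059, with medians of -0.42, -0.45, -0.29 and 1.44. In the authors' table the IL-2/STAT5-responsive and glycolysis lists gave 0.137 and 0.181, and with all 4 arrays above background Th17 genes gave 0.061. The fifth of genes with the brightest signal had a median log2 difference of -0.36 and the fifth with the dimmest 0.92. Camera compared each list with all other genes, not with genes of like brightness. A list median near these values, such as -0.44 for glycolysis, is therefore not shown to differ from genes of like brightness. The same limit holds for the marker lists and gene families below.

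The remaining T cell lists were not called by camera. Of 13 AP-1 genes Fos rose (1.23 ± 0.19, camera adjusted p = 0.43 for the list), and the list's median of -0.28 turned to 0.20 without array 1 labelled Junb-deficient, while without array 2 the list was called (-0.33, adjusted p = 0.031). In TGF-β signalling (20 measured, adjusted p = 0.58), Itgae and the repressor Tgif1 (1.06) rose and Pmepa1 (-1.22) fell, and Itgav gave -0.79. Among 20 T cell receptor response genes (adjusted p = 0.58) Irf8 (-2.02) and Myc (-1.27) fell and Tnfrsf9 (1.21) rose. Of 17 inhibitory and costimulatory receptors (adjusted p = 0.69), Cd244a (1.67) and Tnfrsf9 rose and Ctla4 fell, and Cd160 gave 1.37. Of 23 chemokine receptors and integrins (adjusted p = 0.86), Itgae and Itga1 (2.55) rose and Ccr4 fell, and Ccr2, not called, was at least 3.46-fold higher. Of 21 apoptosis genes (adjusted p = 0.15) Bcl2l11, which encodes the death-promoting protein Bim, rose (1.74), and Bik (-1.38) fell. Naive and resting T cell genes (18, adjusted p = 0.58) had no member called, with Il7r at 1.25 and Igfbp4 at -0.87. Interferon-stimulated genes (16, adjusted p = 0.45) held 2 called, Oasl1 (1.64) and Oasl2 (1.72, above background on 1 control). The stress response list (20, adjusted p = 0.15) had none called, with Hsp90b1 at -0.87 and Sdf2l1 at -1.22. Its median of -0.50 rested on single arrays: the list was called without control 1 (-0.80, adjusted p = 0.029) and without array 2 labelled Junb-deficient (-0.94, adjusted p = 0.0039), and gave -0.01 without control 2 and 0.16 without array 1 labelled Junb-deficient.

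Markers of other cell types were measured because the cultures could hold such cells and because the extraction label names colon. T cell identity genes were seen on every array (14 measured, camera adjusted p = 0.28), and Thy1 (-0.98) and Cd2 (-1.33) fell. Myeloid markers shifted up (10 measured, median 1.30, or 1.05 with dim signals at their floor). Camera gave an adjusted p of 0.032, and of 0.657 with an estimated correlation. All 10 were positive and none was called over all genes. Cd14 (above background on 1 control) gave 2.57 and Siglech 0.71. The Siglech probe read 36570 and 35404 on the controls, above Thy1 at 21352 and 20344, so what it reads is not settled. The filter passed only 10 of 18 myeloid markers. Without it the list call was lost, with a median of 0.80 over all 18 (camera adjusted p = 0.17). The call was also lost without control 2 (adjusted p = 0.17) and without array 1 labelled Junb-deficient (adjusted p = 0.086), where the medians were 0.65 and 0.79, and the median was 0.53 in the normexp setting. B cell markers were all 8 positive (median 1.17, adjusted p = 0.056). The list was called without control 1 (1.94, adjusted p = 0.0058) and without array 2 labelled Junb-deficient (1.66, adjusted p = 0.027), and gave 0.74 without control 2. Ms4a1 (3.18) and Ebf1 (1.67) were called, with Cr2 (1.26) and Cd22 (1.2) passing over the list alone. Colon epithelium markers (7 measured, adjusted p = 0.077, median 0.54) held Slc26a3 and Fcgbp, at least 8.78 and 5.85-fold higher, and Krt8, above background on 1 control, at 1.72, and in the normexp setting Slc26a3 gave 0.64 and Fcgbp 0.24, neither called. The list's adjusted p was 0.049 without control 1, 0.139 without control 2 (median 0.88), 0.052 without array 1 labelled Junb-deficient (1.00), 0.228 without array 2 (0.29), and 0.193 for all 18 genes without a filter (0.37). Of the 18 colon genes fixed, 5 were well above background on each control and 8 and 7 on the arrays labelled Junb-deficient. Stromal markers (9, adjusted p = 0.46) held Dcn, at least 6.20-fold higher, or 0.24 on the log2 scale and not called in the normexp setting. CD8 markers (3, adjusted p = 0.25) gave Crtam 1.23 and Cd8b1 0.55, and γδ T and NK markers (3, adjusted p = 0.38) gave Sox13 -0.995, called, and Klrd1 -1.04. Mast cell and erythroid markers had 2 measured each and were not tested as lists, with Kit at 2.61, Fcer1a at 0.51, Hba-a1 at 1.34 and Car1 at 0.39, none of them called.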

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

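The floor, the filter on repeat and purine-rich probes, quantile normalization with the strictest filter and the coding-region Junb probe were chosen after seeing the data. The 1896 calls moved to 453 with quantile normalization, 314 with normexp background and quantile normalization, 589 with quantile normalization and all 4 arrays above background, 1255 with that filter alone, 618 from the authors' log2 signals, 5035 with a trended robust variance (50.3% higher) and 9405 with median scaling (21% higher), which moves the median of all genes from 0.01 to -0.52. Without a filter limma called 0, with 8819 at an unadjusted p under 0.05, and leaving out each array in turn gave 0, with 5388, 8133, 5646 and 4951 at an unadjusted p under 0.05, in fits where 1 genotype has a single array. Every probe, the mean of probes, the floor, and the filter on repeat and purine-rich probes gave 2276, 2015, 1639 and 1987. Of the smaller sets, 434, 296 and 545 were among the 1896 for quantile, normexp and the authors' signals. By the authors' own deposited p-values, 641 accessions had an adjusted p under 0.05. The cause of these changes was not tested.

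With the array number as a replicate block 6851 genes were called, 4759 higher and 2092 lower, and 8 lists, the 6 and also B cell markers (adjusted p = 0.011) and the stress response (0.03). The difference between arrays 1 and 2 correlated at 0.50 across genes between the genotypes (0.57 for genes above background on all 4 arrays), but with 2 numbers, which no label says mark a batch, this does not show pairing, since same-numbered arrays also share a slide row. All 4 arrays lie on 1 slide, so a slide block was not run.

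The 6 list calls became 2 with quantile normalization and 0 of 26 with an estimated correlation (0 also at an unadjusted p under 0.05). Fry, which tests a list against no change rather than against the other genes, called 4, of which 1 was among the 6. Leaving out an array gave 5 to 9 lists, and the other settings 4 to 8. Lists gained included Th1 genes and apoptosis without a filter (adjusted p = 0.019 and 0.017), resting T cell genes with normexp (0.047), AP-1 genes without array 2 labelled Junb-deficient (0.031), and, in several settings each, the stress response and B cell and colon markers. The Junb difference by the 3′ probe ran from -2.85 to 0.65 over the left-out arrays, reversing to 0.65 without array 1 labelled Junb-deficient, and the coding-region probe, at background on both arrays labelled Junb-deficient, gave a fitted -3.55, past the threshold. Among named genes that reversed, Anxa3 and Agap1 turned to 0.42 and 0.31 with the filter on all 4 arrays, which puts another probe in place. Uncalled genes turned as well: Fcer1a to -0.15 with quantile normalization (-0.15 also with all 4 arrays) and -0.0198 with median scaling, Car1 to -0.15 with median scaling, Tbx21 to 0.15 and 0.23 and Hba-a1 to -1.95 and -1.46 without control 2 and without array 1 labelled Junb-deficient. Tbx21 moved to -0.62 without array 2 labelled Junb-deficient and Hba-a1 to 4.64 without control 1. Signal over background limits the 528 higher calls with no control above it.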

Other observations

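The wrong-label, uneven-spot, silent-gene, single-probe, B cell and stress tests below, and the gene families, were chosen only after the results were seen. Some of 16 gene families defined by symbol shifted and others did not, such as solute carriers, with 123 negative and 124 positive. Mitochondrial ribosomal protein genes gave a median log2 difference of -0.67 on the arrays labelled Junb-deficient, with 74 of 75 negative, and proteasome subunits gave -0.54, with 38 of 38 negative (camera adjusted p = 4.26e-14 and 9.87e-08 over 16 families, 0.79 for each with an estimated correlation). The medians were -0.38 and -0.25 with quantile normalization. Replication-dependent histone genes gave -0.93 (32 of 42 negative, adjusted p = 0.0011, or 0.79 with an estimated correlation) and -0.83 with quantile normalization. Vomeronasal receptor genes, which serve pheromone sensing, gave 1.86, with 66 of 67 positive, but 0.19 with normexp background and quantile normalization. These 67 passed a filter that the increase itself helps decide, and all 1487 odorant, pheromone and taste receptor probes gave a median of 0.38, with 11.8% above background on both controls and 18.7% on both arrays labelled Junb-deficient.

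The 3′ Junb probe was as bright on the array labelled Junb-deficient 2 as on the controls while the coding-region probe was at background. A control array under the wrong label is argued against, since 91.3% of 1626 genes that differed without that array (unadjusted p under 0.01, at least 2-fold) lay on it nearer the other array labelled Junb-deficient. An uneven spot is argued against by a pixel spread at percentile 39.6 of spots of like brightness. Cross-hybridisation may contribute, because the probe holds a GT repeat and 260 other measured probes with such a repeat were higher on array 2 than on array 1 labelled Junb-deficient by a median of 2.38 log2 relative to probes of like brightness. The Junb probe itself differed by 3.5, a size that 14.3% of GT repeat probes reached. It did not differ between the controls (-0.05) as those probes did (1.58), so the repeat leaves part of the pattern open. A transcript that keeps its 3′ end was not tested. Alone it would leave unexplained why this probe fell to 1053 on the array labelled Junb-deficient 1.

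Most called genes were higher on the arrays labelled Junb-deficient. Release of genes that control cells keep silent stays open, since 96.4% of the higher calls were at least 2-fold with dim control signals at their floor but that floor moved no call across 2-fold, and 893 of the 1576 were above background on both controls. A low signal on probes of any silent gene is a candidate explanation for part, because odorant, pheromone and taste receptor probes had a median of 0.38 against 0.26 for other probes of like control brightness (median of the differences 0.0202, 1487 probes), although the controls differed by as much on them (0.38, number 2 minus 1). Background subtraction of dim probes cannot be told apart from a real excess. Among genes above background on all 4 arrays, 75.7% of calls were higher (95% interval 73.2 to 78.0). That filter kept the same scaling and so cannot test scaling. With median scaling 21% of 9405 calls were higher, with a trended robust variance 50.3% of 5035, and with quantile normalization 77.7% of 453. The excess of higher calls therefore depends on the scaling and on the variance model. Unspecific binding by single probes stays open too. Of 251 other measured probes of the genes called higher, 55.0% were at least 2-fold higher, above the 7.84% for genes not called but not shared by all. For genes called lower, 50.5% of 188 other probes were at least 2-fold lower, against 4.74% for genes not called. This agreement between probes therefore does not set the higher calls apart. GA repeat probes were high (61 of 116 such genes called higher, 0 lower), yet 81.0% of calls were still higher once repeat and purine-rich probes were left out.

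Arrays numbered 1 and 2 differed in the same genes in both genotypes. At least 2-fold higher on number 1 in both were 133 genes and on number 2 were 735, against 35 that differed in opposite ways. Of the 217 genes tested on GT repeat probes, 151 were among the 735, out of 22464 genes tested in all. Between 2 probes of a gene, the difference between numbers had a Spearman correlation of 0.41 across 6419 genes. This argues against effects on single spots. It cannot test an effect of slide row that probes of a gene share, since same-numbered arrays lie in the same row. If the numbers mark separate cultures, which no label says, a stress response in those numbered 2 is a candidate explanation for part. The stress list was higher on number 2 by at least 0.55 log2 in both genotypes (number 1 minus 2: -0.55 and -0.88). Chac1 read 1012 and 531 on number 2 and 27.8 and 17.6 on number 1. Whether B cells and red cell precursors were carried into separate cultures numbered 1 could not be settled. The B cell median was higher on number 1 by only 0.28 in the genotype with the smaller difference. Blnk, though, read 167 and 178 on number 1 and 11.45 and 9.03 on number 2, and Hba-a1 2078 and 2961 against 20.7 and 51.6. The naive CD4+CD62LhighCD44lowCD25− sort in the labels would remove both cell types.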
